A study of Triticum aestivum with 18 samples.

How the data were processed

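Roots of the winter wheat cultivar Hereward were dug up at booting in 2011 from the Broadbalk long-term field experiment at Rothamsted, in which nutrients have been withdrawn from the fertiliser of continuous wheat plots. The labels' protocol dates the withdrawal of N, P, K and Mg fertiliser to 1843 and that of S to 2000, while the sample titles speak of low nitrogen for the N group and of no K, Mg, phosphate or sulfate for the others. There were 6 groups of 3 root samples, a nutrient-replete control and plots low in K, Mg, N, P or S, and each of the 18 samples was hybridised to its own Affymetrix Wheat Genome array. The series text gives the number of samples as 12, while 18 were deposited, and all 18 were used. Biotin-labelled cRNA was made from 500 ng of total RNA with a 3' IVT Express kit, per the labels' protocols. The series text speaks of triplicate excavation and of a control plot, and does not say how many plots each treatment had. If the arrays of a group come from 1 plot, p-values measure the spread within that plot, and plot and treatment cannot be told apart.

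The authors deposited 1 intensity per probe set and array on a linear scale, and the submitters' processing notes name Affymetrix Expression Console and the MAS5 algorithm. The software versions, the scaling target and the way samples were assigned to plots are not given in the sources used here. Every deposited intensity was above 0. The mean after removal of the highest and lowest 2% of values was 500.1 on every array, so the arrays had been scaled to a common trimmed mean. Quantiles were not equalised: array medians ran from 53.3 to 72.4, and the highest value per array from 26466 to 41929. Detection calls were not used here, so a probe set at a few units of intensity cannot be separated from background, and its fold changes are uncertain. The number of arrays limits the precision.

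The array table held 61290 probe sets. The 111 control probe sets were left out, and of the 61179 wheat probe sets the 34255 (56%) at or above the array's own median on at least 3 of 18 arrays were tested. Intensities were turned to log2 with no added constant. Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which gave 12 residual degrees of freedom and 4.39 prior degrees of freedom. Adjusted p-values of single probe sets are from limma with Benjamini-Hochberg adjustment over the 34255 probe sets, two-sided, unless another set is named, and those of gene groups are described below. A probe set was called at an adjusted p under 0.05. Each deficiency was compared with the control, and also with the equally weighted mean of the other 4 deficiencies, a contrast without control arrays. A moderated F-test asked for any difference among the 6 groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

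Gene names came from the platform's annotation table, which gave 1 gene for 1273 wheat probe sets, several genes for 0 and none for 59906. Of the 771 genes, 770 were matched by gene number to the RefSeq table of assembly IWGSC CS RefSeq v2.1, which was used for names only, and 1 was not. Of these genes, 102 had a symbol or synonym other than a running LOC number, and 75 of the 102 had a tested probe set. Most called probe sets therefore have no gene name here, and the named genes are a small sample of each response. Probe sets whose names end in _x_at, _s_at or _a_at can hybridise with several related transcripts, which in hexaploid wheat includes the copies on the other genomes.

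Before the data were examined, the tests, the alternatives, 30 gene lists and a rule for named genes had been fixed. The rule took, among called probe sets with an informative gene name whose arrays did not overlap between the groups, the 10 largest rises and the 10 largest falls per comparison with control, with 1 probe set per gene (the smallest p), and 5 per direction for the other contrasts. Because most probe sets were unnamed, the rule's fallback, the 2 largest rises and the 2 largest falls without a gene name, was given as well. These too were taken among called probe sets whose arrays did not overlap. Unnamed probe sets are given by their rank and values, without array identifiers. The lists were matched on symbols and synonyms. Only 3 lists had a tested gene, 1 each: class III peroxidases (PER1), drought and cold (LEA1) and heat shock (hsp16.9A). No list had the 5 genes set as the minimum for the planned list tests, so the tests of the lists for each plot's own nutrient could not be made. In their place, 13 groups were formed from the named genes after the annotation had been read and before any expression test. Each gene of a group was represented by its brightest probe set, and the 6 groups with 5 or more genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 6 groups within a contrast. With that setting 12 of the 60 group tests were called, and 0 of the 60 were called when the correlation was estimated from the data.

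Alternatives were quantile normalization, centring on the 75th percentile, no filter, a stricter filter, a constant of 16.1 added before log2, no intensity trend, only the arrays of the groups compared, the replicate number as a block, and leaving out each array in turn. On 34255 simulated probe sets for low P against control, the procedure recovered 19.4% of 67 changes of 0.50 log2, 59.7% of 67 changes of 1 and 81.8% of 66 changes of 2, with 9 unchanged probe sets among 116 calls. Few probe sets were changed there, and the noise was drawn independently for each. The rates therefore need not hold for the real comparisons, where counts of calls and ties between probe sets differ.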

Results

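The 18 arrays compared wheat roots from a replete control plot with roots from plots low in K, Mg, N, P or S, with 3 arrays per group. The design asks how root transcripts differ under long-term lack of each nutrient. The first principal component of the tested probe sets held 21% of the variance and the second 10.9%. On the first, the low P arrays lay at 42.5 to 63.9 and the low K arrays at -53 to -33.2. On the second, the low N arrays lay at -59.3 to -37.3. Control arrays 1 and 3 lay at -66.2 and -52.8 on the first component and control array 2 at 12.3, close to the low Mg arrays (13.9 to 18.3) and the low S arrays (13.3 to 36.8). The array medians also differed along this component. They were 53.3 to 62 in control arrays 1 and 3 and low K, and 60.1 to 61.1 in low N. In control array 2, low Mg, low P and low S they were 65.2 to 72.4. Whether the first component reflects the intensity distributions or the groups was not tested. Correlations between arrays of a group ran from 0.9551 to 0.9718 over 18 pairs, and between groups from 0.9323 to 0.9736 over 135 pairs. The F-test called 4842 of 34255 probe sets (14.1%). Without low N array 1 it called 3075, without low N array 3 2812, and without low P array 3 2558.

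**Figure D1:**
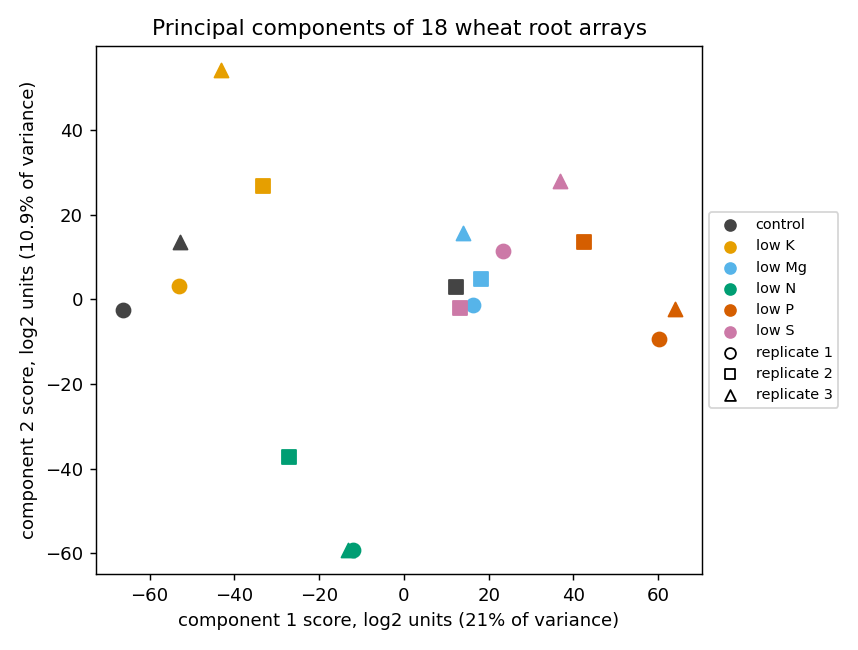
Scores of the 18 arrays on the first 2 principal components of the log2 intensities of the tested probe sets, coloured by group. Low P arrays have the highest scores on the first component (42.5 to 63.9), low N arrays the lowest on the second (-59.3 to -37.3), and control array 2 (12.3 on the first) lies apart from control arrays 1 and 3 (-66.2 and -52.8).

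Low P against control gave 3257 called probe sets, 9.51% of those tested, of which 1434 rose and 1823 fell. LEA1, a late embryogenesis abundant protein of the kind that accumulates in drying tissue, rose by 1.57 ± 0.28 log2 (SE; adjusted p = 0.00407), from an intensity of 5127 ± 2080 in the control to 14580 ± 2560 in low P roots (SD, n = 3 each). Rab15, an abscisic acid responsive dehydrin, rose 3.36-fold on the probe set chosen by the naming rule (1.75 ± 0.38 log2, adjusted p = 0.011), from 3410 ± 1400 to 10930 ± 1740. The other Rab15 probe sets gave log2 differences from 0.32 upward, and 1 of the 3 passed the test. PCS1, a phytochelatin synthase that makes metal-binding peptides from glutathione, rose 1.39-fold (0.48 ± 0.13 log2, adjusted p = 0.0341).

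Of the 5 histone genes, each on its brightest probe set, 3 fell in low P roots and 2 did not pass the test, with a median log2 difference of -0.48. The group test gave adjusted p = 0.00225 with the preset correlation and adjusted p = 0.282 with an estimated correlation. All 6 tested probe sets of H2A-9 were called lower, and the one chosen by the naming rule fell by 1.19 ± 0.21 log2, from 1495 ± 241 to 678.1 ± 232 (adjusted p = 0.00371). H2A-3 fell by 0.78 ± 0.16 log2 (adjusted p = 0.00852) on 1 of its 2 probe sets, while the other stood at 0.09. For wcH2B-8, 4 of 7 probe sets were called lower, the one chosen by the rule at -0.63 ± 0.16 log2 (adjusted p = 0.0252). After quantile normalization 2 of the 5 histone genes passed the test instead of 3, and without control array 3 none of the 3 brightest probe sets did, while the H2A-9 probe set given above stayed called whichever array was left out.

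Among cytoskeletal genes, Tubb5, a beta-tubulin, fell by 0.77 ± 0.11 log2, from 3234 ± 417 to 1898 ± 303 (adjusted p = 0.00119), and all 4 of its probe sets were called lower. It was the only one of 6 tubulin genes to pass the test. The tubulins had a median of -0.24, with adjusted p = 0.00225 in the group test and adjusted p = 0.282 with an estimated correlation. PEAMT1, the phosphoethanolamine methyltransferase that leads to choline, fell by 0.74 ± 0.12 log2, from 11080 ± 967 to 6630 ± 860 (adjusted p = 0.00218). FKBP70, a peptidyl-prolyl isomerase, fell by 0.46 ± 0.07 log2 (adjusted p = 0.00121). The plasma membrane proton pump gene ha1 fell by 0.38 ± 0.10 log2 on 1 of 3 probe sets (adjusted p = 0.0219). Of 4 LEA, dehydrin and Em genes on their brightest probe sets, LEA1 rose and 3 did not pass. In the same arrays the 5'/3' intensity ratio of a ubiquitin control gene, a measure of RNA integrity, ran from 1.09 to 1.12, against 1.19 to 1.28 in the control. The ratios of the G6PDH and sucrose synthase control genes did not separate low P from the control. The G6PDH 5'/3' ratio ran from 0.0436 to 0.0527 in low P, within 0.0393 to 0.0681 in the control. The sucrose synthase middle/3' ratio ran from 0.0715 to 0.0872, within 0.0712 to 0.0989. Single control probe sets did differ. The 3' probe set for CYP86 fell by 1.19 log2 in low P (limma, adjusted p = 0.00193 over the control sets), while its 5' probe set stood at 0.19. In low P the 18S rRNA probe set lay below all control arrays and several GAPDH probe sets above them, none at an adjusted p under 0.05.

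Of the unnamed probe sets with non-overlapping arrays, the largest rise in low P roots was 6 ± 1.56 log2 (adjusted p = 0.0256), where the control arrays spread from 1.482 to 1413. The next was 5.76 ± 0.86 log2 (adjusted p = 0.00142), where the control stood at 2.436 ± 0.352, so neither fold is well fixed. The largest falls were -3.85 ± 0.70 log2 (adjusted p = 0.00463) and -3.68 ± 0.35 log2, from 263.5 ± 44.1 to 21.65 ± 9.36 (adjusted p = 6.91e-05). All 3 arrays of low P lay beyond all 3 of the control for 25% of tested probe sets, where chance gives 10%. The count of 3257 became 5041 without control array 2 (2674 higher, 2367 lower), 847 without control array 3, 1351 without low P array 1, 1250 without low P array 3, and 149 with only the 6 arrays compared. In the 6-array fit the calls of LEA1, PCS1, H2A-9, H2A-3, Tubb5, PEAMT1, wcH2B-8, FKBP70 and ha1 were lost, and without control array 3 those of Rab15, PCS1, H2A-3, wcH2B-8 and ha1. PCS1 and wcH2B-8 also lost theirs without low P array 1 or 3, and ha1 without control array 1 or low P array 1 or 2.

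**Figure D2:**
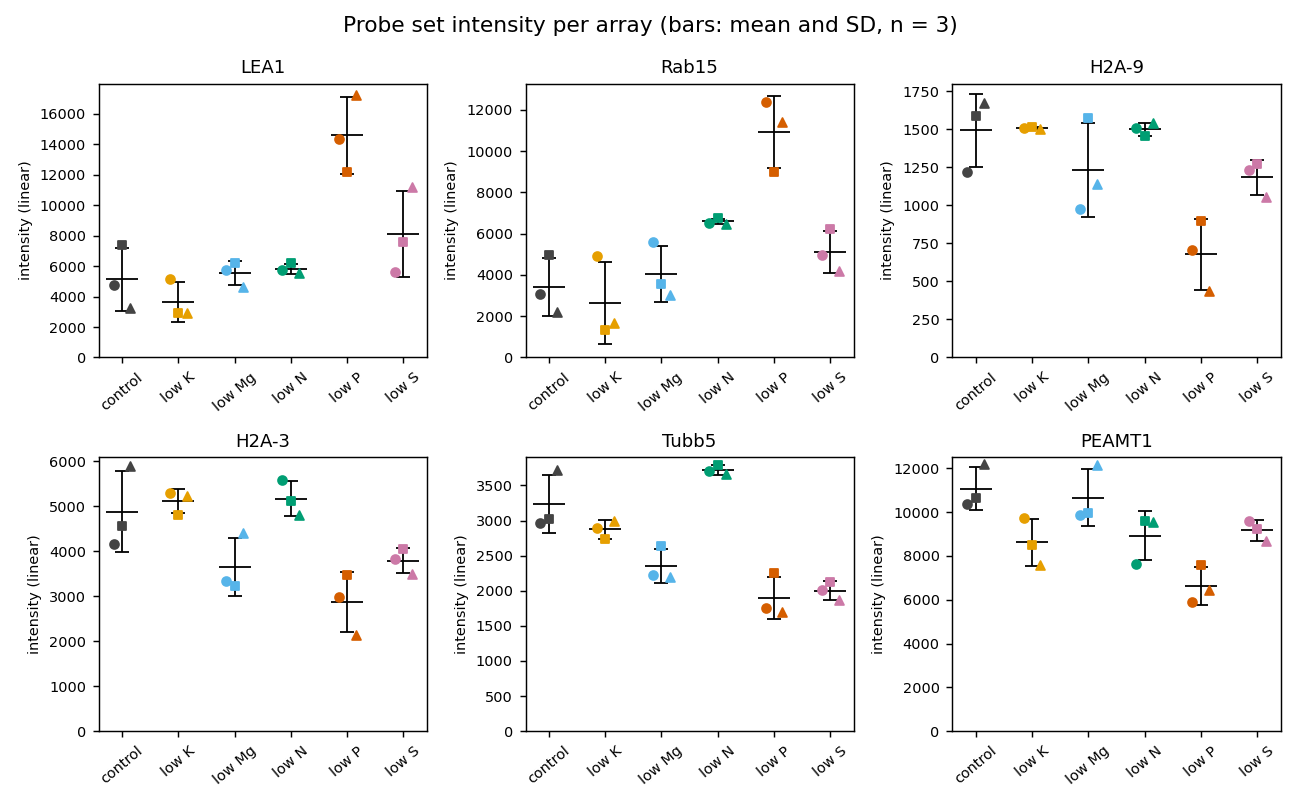
Linear array intensity (vertical axis) of LEA1, Rab15, H2A-9, H2A-3, Tubb5 and PEAMT1 in the 6 groups, with a symbol per array and bars for the mean and SD (n = 3). In low P roots LEA1 (14580 ± 2560) and Rab15 (10930 ± 1740) lie above the control, and H2A-9 (678.1 ± 232), H2A-3 (2872 ± 676), Tubb5 (1898 ± 303) and PEAMT1 (6630 ± 860) lie below it.

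Against the mean of the other 4 deficiencies, low P roots differed at 3695 probe sets, 1461 higher and 2234 lower. LEA1 was higher by 1.41 ± 0.22 log2 (adjusted p = 0.0012) and Rab15 by 1.40 ± 0.30 log2 (adjusted p = 0.00802). H2A-9 fell by 1.05 ± 0.16 log2 (adjusted p = 0.00119), PEAMT1 fell by 0.49 ± 0.09 log2 (adjusted p = 0.00423) and FKBP70 fell by 0.37 ± 0.05 log2 (adjusted p = 0.00064) relative to that mean. Of the 5 histone genes, 4 were lower and 1 did not pass, with a median of -0.43 (adjusted p = 0.00148, and adjusted p = 0.256 with an estimated correlation). The tubulins had 1 lower of 6 and a median of -0.17 (adjusted p = 0.0147, and adjusted p = 0.256 with an estimated correlation). Among called probe sets with non-overlapping arrays, the unnamed extremes of this contrast were 4.42 ± 0.76, 3.30 ± 1, -4.31 ± 0.46 and -3.61 ± 0.81 log2. The count was 1495 without low P array 1 and 1088 without low P array 3. Leaving out either low P array ended the call of Rab15, leaving out array 3 ended those of the 4 histone genes, and leaving out array 1 those of wcH2B-8 and wcH2B-6.

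Low N against control gave 142 called probe sets, of which 25 rose and 117 fell. No called gene had an informative name, and the following were listed under a running number only, which was chosen as a reason to name them after their values were seen. LOC543150 had both probe sets lower: the more responsive fell by 1.87 ± 0.26 log2, from 16840 ± 473 to 4933 ± 2290 (SD, n = 3 each; adjusted p = 0.00278), and the other fell by 0.65 ± 0.13 log2 (adjusted p = 0.0351). LOC100125738 fell by 0.69 ± 0.13 log2 (adjusted p = 0.0278), LOC543105 fell by 0.57 ± 0.11 log2 on 1 of 2 probe sets (adjusted p = 0.0317), LOC780641 fell by 0.48 ± 0.10 log2 (adjusted p = 0.0415) and LOC543390 fell by 0.47 ± 0.09 log2 (adjusted p = 0.0267). LOC543453 rose by 0.68 ± 0.13 log2 (adjusted p = 0.0318). The largest falls were at 2 unnamed probe sets, from 477.6 ± 336 to 7.842 ± 1.34 (-5.72 ± 0.53 log2, adjusted p = 6.45e-05) and from a mean of 9633 to a mean of 184.7 (-5.68 ± 0.64 log2, adjusted p = 0.000419). The largest rises among the unnamed were 4.27 ± 0.86 log2 (adjusted p = 0.0415), where the control stood at 2.436 ± 0.352, and 3.21 ± 0.66 log2 (adjusted p = 0.044). Non-overlapping arrays were found for 15.9% of probe sets, where chance gives 10%. The count was 58 without control array 1, 88 without control array 3, 65, 66 and 67 without low N arrays 1, 2 and 3, and 57 with only the 6 arrays compared. The larger LOC543150 fall and the 2 largest unnamed falls stayed called whichever array was left out, and each of the other probe sets given here lost its call without at least 4 of the 6 arrays in turn.

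Against the mean of the other 4 deficiencies, low N roots differed at 3961 probe sets, 2097 higher and 1864 lower. Changes of the other deficiencies enter this count too, and against the control low N gave 142. Of the 4 photosynthesis genes tested, 3 were lower in low N than that mean under each of the 3 scalings, with a median of -1.12 log2, and rbcl, encoding the large subunit of Rubisco, did not pass on its brightest probe set. PsbP, of the oxygen-evolving complex of photosystem II, stood at 141.5 ± 14.9 in low N (SD, n = 3) and 471.5 ± 161 in the others (n = 12), a difference of -1.65 ± 0.28 log2 (adjusted p = 0.00208). PsbO, of the same complex, stood at 198.8 ± 19.4 against 483.6 ± 194 (-1.19 ± 0.30 log2, adjusted p = 0.0204), and petC, the Rieske iron-sulphur protein, at 125 ± 7.26 against 276.9 ± 104 (-1.05 ± 0.30 log2, adjusted p = 0.0326). For rbcl 3 of 7 probe sets were called lower, with log2 differences from -1.47 to 0.19. Against the control 0 of the 4 genes were called by limma in low N: PsbP stood at -1.16 log2 (adjusted p = 0.208), PsbO at -0.60 (adjusted p = 0.588) and petC at -0.59 (adjusted p = 0.578). The photosynthesis median against the control was 0.84 in low S and 0.50 in low Mg, which adds to the difference from the other deficiencies. The calls of PsbO and petC were lost when any 1 low N array was left out, and that of PsbP was not.

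In the same contrast 6-FEH, a fructan exohydrolase that degrades stored fructan, was higher by 1.26 ± 0.18 log2 (adjusted p = 0.000616), at 280.6 ± 44.9 against 117 ± 17.8. Its difference from the control was 1.06 ± 0.23 log2 (adjusted p = 0.051). Tubb5 was higher by 0.73 ± 0.09 log2 (adjusted p = 0.000198), with all 4 probe sets called, although the 6 tubulins together had a median of -0.05. Its intensity was 3719 ± 65.9 in low N, 3234 ± 417 in the control and 1898 ± 303 to 2872 ± 130 in the other deficiencies, and on its brightest probe set the difference from control was 0.23 log2 (adjusted p = 0.394). Of the genes with an informative name, 0 were called by limma in low N against the control, where 3897 probe sets passed at an unadjusted p under 0.05. GSTZ1, a glutathione transferase of the zeta class, was lower on all 3 probe sets, at -0.43 ± 0.10 log2 on the one chosen by the rule (adjusted p = 0.0145), and cys1 was lower at -0.38 ± 0.07 log2 (adjusted p = 0.00434). Of 5 grain storage protein and inhibitor genes 2 were lower, gli-2, a gliadin, at -1.03 ± 0.28 log2 and wci at -1.18 ± 0.32 log2 (adjusted p = 0.0406 for the group, adjusted p = 0.178 with an estimated correlation, and adjusted p = 0.0705 after quantile normalization). LOC780687 was higher by 3.01 ± 0.86 log2. The same 2 unnamed probe sets that fell most against the control stood lowest here among called probe sets with non-overlapping arrays (-5.36 ± 0.51 and -5.14 ± 0.42 log2). The count of 3961 was 1593, 2145 and 1337 without low N arrays 1, 2 and 3, with the majority lower each time (897, 1203 and 707), as after 75th-percentile centring (1678 higher, 1986 lower). Both grain genes lost their calls without low N array 2 or 3, gli-2 also without array 1, and GSTZ1 on the probe set given lost its call without array 3.

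**Figure D3:**
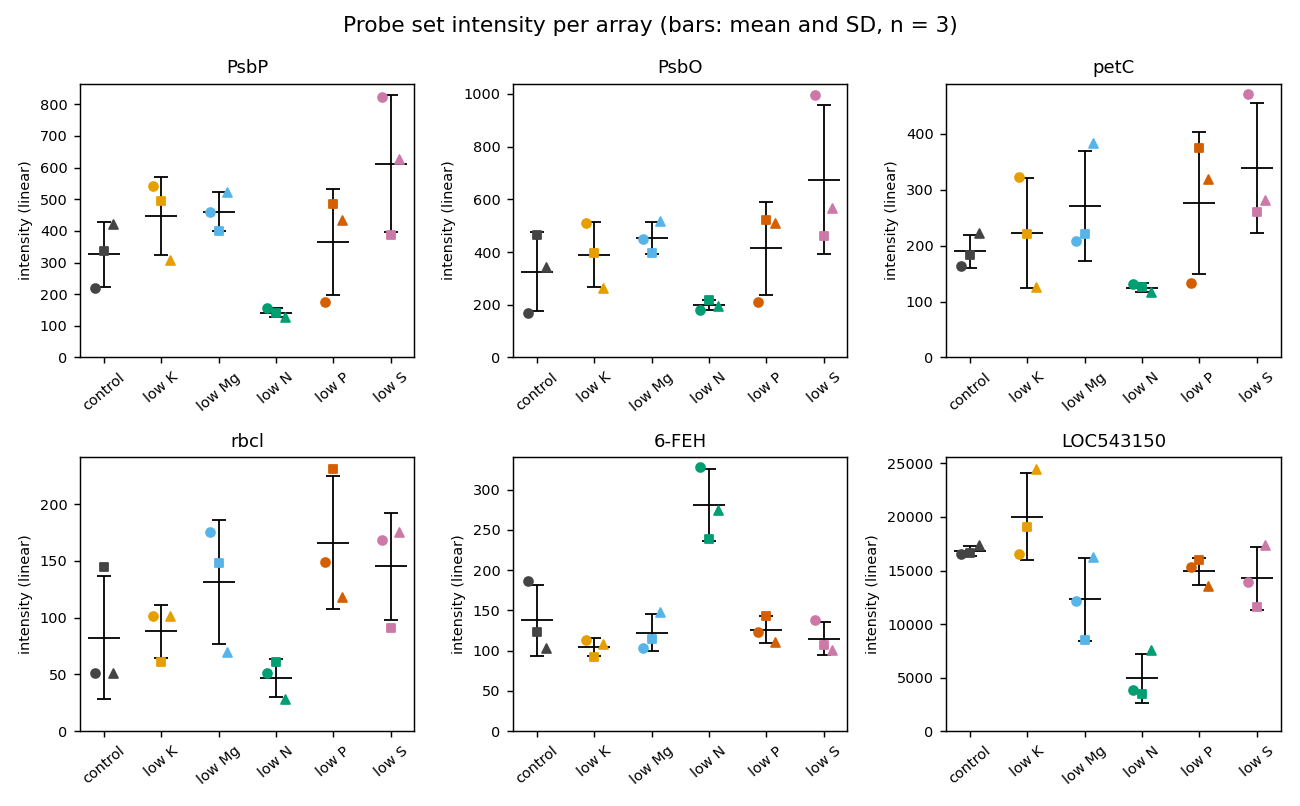
Linear array intensity (vertical axis) of PsbP, PsbO, petC, rbcl (the probe set with the lowest p), 6-FEH and LOC543150 in the 6 groups, with a symbol per array and bars for the mean and SD (n = 3). In low N roots PsbP (141.5 ± 14.9) and petC (125 ± 7.26) lie below all control arrays, PsbO and rbcl overlap the control, 6-FEH lies high (280.6 ± 44.9) and LOC543150 lies below the control (4933 ± 2290 against 16840 ± 473).

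Low K against control gave 70 called probe sets, of which 48 rose and 22 fell. Of the 70, 4 had a gene, each listed under a running number and named after its values were seen. LOC543226 rose 4.03-fold (2.01 ± 0.29 log2, adjusted p = 0.0128), from 648.9 ± 264 to 2523 ± 563 (SD, n = 3 each). LOC606346 rose by 1.04 ± 0.19 log2 (adjusted p = 0.0299), LOC606323 by 0.96 ± 0.17 log2 (adjusted p = 0.0265) and LOC543031 by 0.50 ± 0.09 log2 (adjusted p = 0.0442). Among the unnamed, the largest rises were from 145 ± 22.9 to 873.9 ± 128 (2.59 ± 0.20 log2, adjusted p = 1.49e-05) and from 85 ± 17.5 to 502.6 ± 230 (2.47 ± 0.30 log2, adjusted p = 0.00384). The largest falls were -3.59 ± 0.44 log2, from 67.57 ± 24.6 to 5.635 ± 2.02 (adjusted p = 0.00384), and -1.31 ± 0.25 log2 (adjusted p = 0.0442). None of the 6 tubulin genes was called singly by limma. Their median of 0.20 gave adjusted p = 0.0259 for a rise as a group, adjusted p = 0.462 with an estimated correlation, and adjusted p = 0.525 with the preset correlation after quantile normalization. None of the 8 carbohydrate and glycolysis genes was called by limma, and their median of -0.24 gave adjusted p = 0.0289 for a fall as a group and adjusted p = 0.263 with an estimated correlation.

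Non-overlapping arrays were found for 12.3% of probe sets in low K, where chance gives 10%. The count of 70 was 35 without control array 2, 7 without control array 3, 258, 13 and 6 without low K arrays 1, 2 and 3, where most calls were falls (160, 9 and 4), 6 with no intensity trend and 4 with only the 6 arrays compared. Leaving out control array 3 or low K array 3 ended the calls of all 4 numbered genes and of the smaller unnamed fall, while the other 3 unnamed probe sets kept theirs whichever array was left out. After 75th-percentile centring 52 rose and 10 fell (83.9% higher, against 68.6% as deposited).

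Against the mean of the other 4 deficiencies, low K roots differed at 2813 probe sets, 1243 higher and 1570 lower. Changes of the other deficiencies enter this count too, and against the control low K gave 70. The count depended on the scaling: after centring on the 75th percentile 2231 were higher and 972 lower (69.7% higher, against 44.2% as deposited), and after quantile normalization 1458 were called. Among the 3426 brightest probe sets 756 were called higher as deposited, 138 after quantile normalization and 1180 after 75th-percentile centring. As deposited, 5 of 6 tubulins were higher with a median of 0.39 (adjusted p = 3.65e-07, and adjusted p = 0.0818 with an estimated correlation), among them tubb1 at 0.45 ± 0.09 log2 (adjusted p = 0.00716). After quantile normalization 0 of the 6 were called by limma, with a median of 0.12 (adjusted p = 0.00542 for the group, and adjusted p = 0.465 with an estimated correlation), and all 6 were called after 75th-percentile centring. In the same arrays the middle/3' ratio of a sucrose synthase control gene ran from 0.0569 to 0.0756 in low K, against 0.0715 to 0.116 in the other deficiencies. The mean 5'/3' ratio of a G6PDH control gene was 0.04437, the lowest of the 6 groups. Its range of 0.0371 to 0.0516 overlapped that of low P (0.0436 to 0.0527, mean 0.04687). The ubiquitin 5'/3' ratio was not low in low K, with a mean of 1.25, against means of 1.107 to 1.27 in the other deficiencies. SAHH, S-adenosylhomocysteine hydrolase of the methyl cycle, was higher by 0.47 ± 0.10 log2 (adjusted p = 0.00908) and COMT1, a lignin methyltransferase, by 0.42 ± 0.10 log2 (adjusted p = 0.0175). Both calls were lost after quantile normalization, at 0.13 and 0.07 log2.

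In the same contrast 2 of 5 histone genes were higher (median 0.24, adjusted p = 0.0215, and adjusted p = 0.461 with an estimated correlation), and 0 were called by limma after quantile normalization (adjusted p = 0.307 for the group). The ubiquitin-conjugating enzyme gene UBC1 (also listed as UBC2) was higher by 0.47 ± 0.09 log2 on 1 of 3 probe sets (adjusted p = 0.00607), and the proton pump gene ha1 by 0.45 ± 0.08 log2 (adjusted p = 0.00387), with all 3 probe sets called. After quantile normalization that ha1 probe set stayed called at 0.27 log2, while the brightest lost its call at 0.21. LEA1 was lower in low K, at 3666 ± 1310 (SD, n = 3) against 8514 ± 4160 (n = 12), a difference of -1.13 ± 0.22 log2 (adjusted p = 0.00752). The low P (14580 ± 2560) and low S (8126 ± 2840) means add to that difference, and against the control LEA1 stood at -0.46 log2 in low K (adjusted p = 0.636). Of the genes with an informative name, 0 were called by limma in low K against the control, where 3280 probe sets passed at an unadjusted p under 0.05. Among called probe sets with non-overlapping arrays, the unnamed extremes here were 5.58 ± 1.59, 4.17 ± 1.03, -4.18 ± 0.63 and -4.13 ± 0.86 log2. The lowest of all called differences was -4.84 log2. The count was 1041 without low K array 2 and 516 without low K array 3, and leaving out either ended the calls of LEA1 and COMT1. COMT1 also lost its call without array 1, SAHH and 4 of the 5 tubulins theirs without array 3, and both histone genes theirs without any 1 low K array.

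Low Mg against control gave 21 called probe sets, 18 higher and 3 lower. LOC606323, which was also called in low K, rose by 1.04 ± 0.17 log2 (adjusted p = 0.0397), from 3127 ± 498 to 6443 ± 1270 (SD, n = 3 each). The largest rises were at unnamed probe sets, from 308.6 ± 62.3 to 2986 ± 1460 (3.18 ± 0.42 log2, adjusted p = 0.012), and from 195.6 ± 89 to 1488 ± 510 (3 ± 0.48 log2, adjusted p = 0.0397). The 3 that fell were unnamed and stood at -1.09 ± 0.17, -0.78 ± 0.13 and -0.46 ± 0.08 log2. None of the 6 tubulin genes was called singly by limma. Their median of -0.12 gave adjusted p = 0.0252 for a fall as a group, adjusted p = 0.459 with an estimated correlation, and adjusted p = 0.698 with the preset correlation after quantile normalization. At an unadjusted p under 0.05, 3177 probe sets passed, and non-overlapping arrays were found for 13.1%, where chance gives 10%. The count of 21 was 210 without control array 2, 0 without control array 3, 5 without low Mg array 2, 0 without low Mg array 3, 11 after 75th-percentile centring (72.7% higher, against 85.7% as deposited), and 2 with no intensity trend or with only the 6 arrays compared. Against the mean of the other 4 deficiencies, 3 unnamed probe sets were higher by limma (0.97 ± 0.13, 0.97 ± 0.14 and 0.78 ± 0.11 log2), each at adjusted p = 0.0292, and 1913 passed at an unadjusted p under 0.05. That count fell to 0 without any 1 of 8 deficiency arrays (the 3 of low K, low Mg array 3, low N arrays 2 and 3, low S arrays 1 and 3), and was 10 without low Mg array 1 and 5 without low P array 2.

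Low S against control gave 6 called probe sets by limma, 6 higher and 0 lower, while 4555 passed at an unadjusted p under 0.05. All 6 were also called higher in low P. The largest rise was 1.5 ± 0.23 log2 (adjusted p = 0.0436), at an unnamed probe set, and the next was 1.41 ± 0.16 log2, from 838 ± 108 to 2214 ± 108 (SD, n = 3 each; adjusted p = 0.00221). These 2 probe sets share a cluster number in their array names, so they may not be separate genes. None of the 6 tubulin genes was called singly by limma. Their median of -0.26 gave adjusted p = 5.98e-05 for a fall as a group, adjusted p = 0.218 with an estimated correlation, and adjusted p = 0.0534 with the preset correlation after quantile normalization. Non-overlapping arrays were found for 16.3% of probe sets, where chance gives 10%. The count of 6 was 995 without control array 2 (653 higher, 342 lower), 13 without control array 1, 3 without control array 3, 3 and 2 without low S arrays 2 and 3, 1 with only the 6 arrays compared, and 14 with the stricter filter. The rise of 1.41 log2 was called under every alternative and every leave-out. Against the mean of the other 4 deficiencies limma called 0 probe sets, with 3319 at an unadjusted p under 0.05, 6 called without low P array 1 and 2 without low S array 1. The tubulins had a median of -0.18 in that contrast (adjusted p = 0.000542, and adjusted p = 0.314 with an estimated correlation), and of -0.06 after quantile normalization (adjusted p = 0.196).

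Across the comparisons with control, 3421 probe sets were called at least once, 64 in 2 or more and 11 in 3 or more. In 100 simulations of unchanged groups against the same controls, at most 1 probe set was called in 2 or more. Those simulations used the pooled spread, and the control arrays varied more (mean variance 0.224) than the other groups (0.142 to 0.2), so they can understate chance overlap. Of the 11, 3 unnamed probe sets rose in low Mg, low P and low S, by 0.95, 2.09 and 1.41 log2 in that order for the strongest, by 0.80, 1.31 and 0.98 for the next and by 0.64, 1.31 and 0.98 for the last. LOC606323 rose in low K, low Mg and low P (0.96, 1.04 and 0.92 log2), as did 2 unnamed probe sets. Unnamed probe sets numbering 3 fell in low K, low N and low P, and 1 fell in low Mg, low N and low P (-0.78, -1.35 and -1.16 log2). The last rose by 0.76 log2 in low K and was lower in low N (-0.76) and low P (-0.62). These 11 are given for their repeated calls, after their values were seen. Of the 3 that fell in low K, low N and low P, 2 share a cluster number in their array names and may not be separate genes. The 6 shared rises of low P and low S compare with 0.251 for independent lists and at most 1 in the simulations. Of the 6, 2 also share a cluster number. Part of the excess may come from the shared control arrays, since 3 arrays cannot be divided between 2 comparisons with 2 or more each. The number called in 2 or more was 954 without control array 2, 13 without control array 3, 164, 26 and 40 without low K arrays 1, 2 and 3, 34, 25 and 40 without low N arrays 1, 2 and 3, 41 without low Mg array 3, 35 without low P array 3, 41 and 33 without low S arrays 2 and 3, and 15 with no intensity trend.

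**Figure D4:**
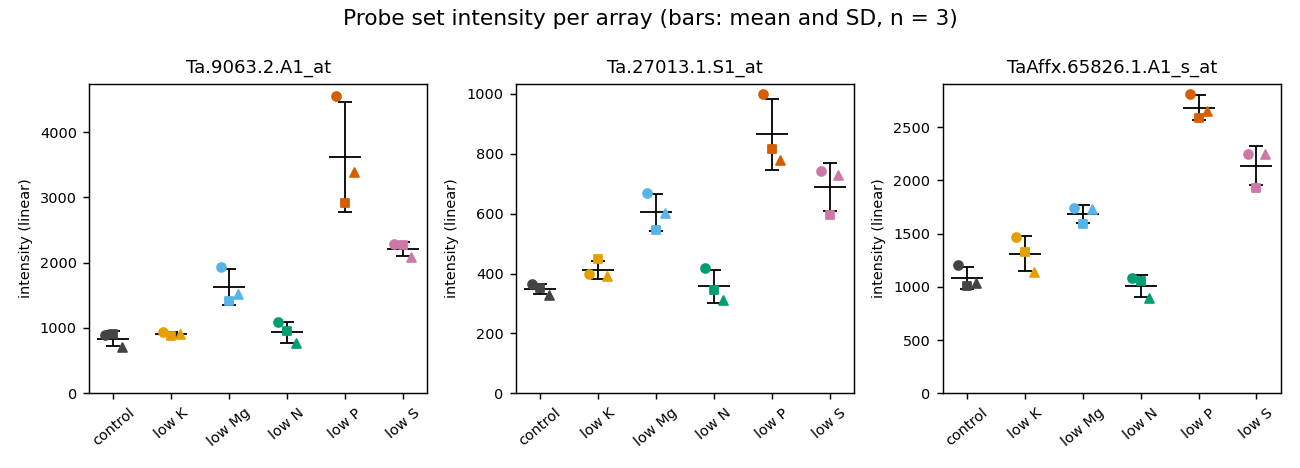
Linear array intensity (vertical axis) of the 3 unnamed probe sets that rose in low Mg, low P and low S, in the 6 groups, with a symbol per array and bars for the mean and SD (n = 3). Each was called higher than the control in low Mg, low P and low S, and the first stood at 838 ± 108 in the control and 2214 ± 108 in low S.

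The 3 genes from the lists fixed beforehand were PER1, LEA1 and hsp16.9A. PER1, a class III peroxidase, gave log2 differences from control of -0.06 in low K, 0 in low Mg, -0.15 in low N, -0.16 in low P and -0.08 in low S (SE 0.23) on its brighter probe set, and its other probe set stood at 0.81 in low Mg, 0.64 in low N and -0.73 in low S, none of them called. The small heat shock protein hsp16.9A gave -0.71, -0.28, -0.18, -0.39 and 0.20 in that order (SE 0.57), none called. LEA1 gave -0.46, 0.18, 0.26, 1.57 and 0.69 (SE 0.28), and its low P rise was called over all probe sets (adjusted p = 0.00407). Its low S difference gave adjusted p = 0.321. Each list held 1 tested gene, so a count adjusted over the list alone would rest on an unadjusted p and is not given.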

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

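No difference met the rules set beforehand for a closer look, as they were applied here, and 3 patterns seen in the arrays are weighed below. The screen took only rises among the 25 wheat control probe sets. All 3 arrays had to lie above all 3 of the control, with an adjusted p under 0.05 over the control sets. Falls and the other probe sets were not screened. The swap and RNA quality tests, both shared control tests, and quantile normalization without control array 2 were chosen only after the result was seen. The other tests were written down before.

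Control array 2 stood apart from control arrays 1 and 3: its mean correlation with them was 0.9603, against 0.9694 with the low Mg arrays and 0.9695 with the low S arrays, and no biological explanation was tested. A shift in its intensity distribution was tested by the low S count after quantile normalization without control array 2. That count was 226, against 6 with the array kept, so such a shift did not account for all of the low S change. The matching counts were 28 and 20 for low Mg, 158 and 153 for low N, 4273 and 3412 for low P, and 10 and 49 for low K. As deposited, low Mg gave 210 without the array and 21 with it. The distance of control array 2 after normalization was not measured, so a shift stays open as part of the cause. The correlations argued against a swap with a low Mg or low S array. Of those 6 arrays, 0 were closer to control arrays 1 and 3 (0.9528 to 0.9613) than to their own group (0.97 to 0.9712). Such a swap was not excluded, because the test takes control arrays 1 and 3 to stand for every true control array. For RNA quality, 1 of 3 control genes had a ratio (5'/3', or middle/3' for sucrose synthase) outside the range of the other controls (ubiquitin, 1.19 against 1.28 and 1.28), which leaves RNA quality undecided. A swap with a low K, low N or low P array was not tested, and a wrong label on control array 2 without a partner among these 18 arrays stays open.

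Bright probe sets were higher in low K than in the other deficiencies, with a median log2 difference of 0.12 among the 3426 brightest. A stretched bright end of the scale in the low K arrays fits this pattern: after quantile normalization the median was 0.01. Of the tubulin genes, 5 of 6 passed as deposited and 0 of 6 after quantile normalization, which a stretched bright end also fits, yet all 6 stayed higher (median 0.12, against 0.39), with adjusted p = 0.00542 for the group and adjusted p = 0.465 with an estimated correlation. A rise of abundant transcripts in roots low in K was not excluded, because quantile normalization would also take away a real shift of that kind, so these values do not show which it was.

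Differences from control in low Mg, low P and low S went together, with correlations of 0.72 (low Mg and low S), 0.67 (low P and low S) and 0.66 (low Mg and low P), where simulated unchanged groups gave 0.5 for each pair. Their covariances were 0.1272, 0.1599 and 0.1481 in that order, against 0.03778 to 0.09061 in the other 7 pairs and 0.05121 to 0.05135 in the simulation, which was set aside because the control arrays varied more (mean variance 0.224) than the other groups (0.142 to 0.2). Without control array 2 the mean covariance of these 3 pairs was 0.256, against 0.145 with all arrays. That of the other 7 was 0.14, against 0.0619. The means of these 3 pairs and of the other 7 differed by 0.0831 (jackknife SE 0.0349), but the pairs were picked for their high values. The smallest of the 3 exceeded the highest of the 7 by 0.0366 (jackknife SE 0.0224), under 2 SE. This leaves open whether the gap is more than the spread of the arrays and the picking of the pairs. The 3 shared control arrays add the same covariance to every pair, which cancels in such a difference, so the gap does not decide about them. The shared control arrays stay open for the level itself. With a different control array for each group, the smallest mean covariance was 0.0551 (low Mg and low S, 0.00387 to 0.13 over 6 choices, SD 0.0581). The others were 0.076 (low Mg and low P) and 0.0878 (low P and low S). All were above 0 in all choices but by less than their SD in some, against -0.0343 to -0.0166 for the pairs with low K. A common response in these 3 deficiencies, opposite changes in low K and a further structure of the arrays were not separated. The covariances were taken on the deposited scale only, so differences in the arrays' intensity distributions were not separated either.

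In each comparison with control, 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 70 and 95 for low K, where 2 splits reached the real count, and 21 and 1 for low Mg, 142 and 2 for low N, 3257 and 74 for low P, and 6 and 1 for low S, where 1 split did, the real one. Against the mean of the other deficiencies, 1 of 100 splits (the real one) reached the count for low K, low N and low P. The real count and the highest other were 2813 and 246, 3961 and 1081, and 3695 and 1245 in that order. These splits mixed the arrays of all the deficiencies, so real differences between groups entered their spread and could lower their counts. They therefore argue against interchangeable arrays over all the deficiencies, and do not exclude chance for any 1 contrast. For the F-test 1 of 100 splits reached the real count (4842, highest other 29), which excludes chance only for the 6 groups together. No split tests an effect shared by the arrays of 1 plot. For low Mg against the mean of the other deficiencies, 3 of 100 splits reached the real count of 3. The highest other split gave 1529 calls, and the reason was not tested. For low S against that mean the real count was 0 by limma (3319 at an unadjusted p under 0.05), which any split reaches (100 of 100; highest other 535), so the splits say nothing about chance there.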

How the results depend on the processing

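Of the alternatives, only quantile normalization without control array 2 was chosen after the data were seen. Leaving out each array in turn gave 1308 values for the 131 called items, of which 972 stayed called in the same direction, 336 lost the call and 0 reversed. The other alternatives gave 1027 values: 840 stayed called, 186 lost the call and 1 reversed. That 1 was TEF1 in low K against the other deficiencies, 0.30 log2 as deposited and -0.06 after quantile normalization, and the cause was not tested. With no intensity trend the counts were 6 for low K, 2 for low Mg, 51 for low N, 0 for low Mg against the other deficiencies, 2986 for the F-test and 15 for probe sets called in 2 or more comparisons; the cause was not tested. With only the arrays of the groups compared they were 4 for low K, 2 for low Mg, 57 for low N, 149 for low P and 1 for low S, and 0 for low Mg against the others with only the 15 deficiency arrays, where fewer arrays estimate the spread. Low Mg gave 11 after 75th-percentile centring, low S 14 with the stricter filter (fewer probe sets tested), and low K against the others 1458 after quantile normalization and 1485 higher and 1230 lower with the stricter filter. Quantile normalization without control array 2 gave 10 for low K and 226 for low S (161 higher, 65 lower). Replicate numbers do not pair the arrays: residual correlations of equal numbers ran from -0.10 to 0.11, and 4, 3, 2, 2 and 0 of 6 arrays correlated best with their own number in low K, Mg, N, P and S. With the replicate block the counts were 72 for low K, 19 for low Mg, 3266 for low P and 13 for low S, and 0 for low Mg against the others.

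Leaving out 1 array, counts ran from 6 (low K 3) to 258 (low K 1) for low K, 0 (control 3) to 210 (control 2) for low Mg, 58 (control 1) to 196 (control 2) for low N, 847 (control 3) to 5041 (control 2) for low P, and 2 (low S 3) to 995 (control 2) for low S. Against the other deficiencies they ran from 516 (low K 3) to 2957 (low P 2) for low K, 0 (low K 1) to 10 (low Mg 1) for low Mg, 1337 (low N 3) to 4484 (low K 1) for low N, 1088 (low P 3) to 3738 (low P 2) for low P, and 0 (low K 1) to 6 (low P 1) for low S. The F-test ran from 2558 (low P 3) to 6675 (control 2), and probe sets called in 2 or more comparisons from 13 (control 3) to 954 (control 2). Of the genes that were not called, PER1 ran from -0.23 to 0.11 log2 in low K and -0.29 to 0.14 in low S, LEA1 from -0.11 to 0.48 in low Mg and -0.02 to 0.56 in low N, and hsp16.9A from -0.66 to 0.16 in low Mg, -0.40 to 0.19 in low N, -0.99 to 0.12 in low P and -0.26 to 0.66 in low S. Items below the stricter filter have no value there, the lists for each plot's own nutrient could not be tested, and signal over background limits the dim probe sets.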

Other observations

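Several named genes not described above differed between 1 deficiency and the mean of the other 4, each on its brightest probe set. WGA2, a wheat germ agglutinin, was higher in low P by 0.58 ± 0.16 log2 (adjusted p = 0.027), at 8722 ± 328 (SD, n = 3) against 6014 ± 1540 (n = 12), and was the only 1 of 4 defence-related genes called. PCS1 was higher in low P (0.34 ± 0.11 log2, adjusted p = 0.0468) and lower in low N (-0.45 ± 0.11 log2, adjusted p = 0.0131), at 984.5 ± 122 and 639.5 ± 114. In low N roots the small subunit of ADP-glucose pyrophosphorylase, AGP-S, was higher by 0.29 ± 0.09 log2 (adjusted p = 0.0448), the initiation factor eIF-2-beta by 0.17 ± 0.05 log2 (adjusted p = 0.0461) and H2A-3 by 0.46 ± 0.13 log2 (adjusted p = 0.027). The elongation factor gene TEF1 was higher in low K by 0.30 ± 0.07 log2 (adjusted p = 0.016), and stood at -0.06 after quantile normalization. The calls of WGA2, H2A-3 and TEF1 were lost without any 1 array of the deficiency named, that of PCS1 in low N without low N array 3, and those of AGP-S, eIF-2-beta and PCS1 in low P without at least 11 of the 15 deficiency arrays in turn.

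The photosystem genes that were lower in low N than in the other deficiencies stood high in low S without being called by limma: PsbO at 675.1 ± 284 and PsbP at 612.6 ± 218, differences from control of 1.09 and 0.90 log2 (adjusted p = 0.262 and adjusted p = 0.303). Of the 3 gibberellin 20-oxidase genes, 0 were called in any contrast. None of the 7 translation genes was called against the control, and of the metal and root exudation group PCS1 in low P was the only 1 of 4 called against it on its brightest probe set. No thionin gene was tested. Among the array's 25 wheat control probe sets, which were kept out of the counts, the 3' sucrose synthase probe set fell by 0.41 log2 in low N (adjusted p = 0.0157 over the control sets), from 16940 ± 1780 to 12700 ± 638. Its middle and 5' probe sets stood at -0.26 and -0.4 log2 and did not pass. The 3' probe set for the cytochrome CYP86 fell by 1.19 log2 in low P (adjusted p = 0.00193 over the control sets), from 188.7 ± 28.8 to 84.03 ± 21.9, while its 5' and middle probe sets stood at 0.19 and 0.01 log2.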
